A study of Mus musculus with 6 samples.

How the data were processed

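Gene expression was measured by RNA sequencing in whole left lungs of adult wild-type C57BL/6 mice, an inbred laboratory strain. The labels give 3 lungs from naive mice and 3 lungs in which the left pulmonary artery was tied for 4 h and blood flow then restored for 24 h, a warm ischemia-reperfusion injury. Per the labels' protocols, the lungs were kept in RNAlater, an RNA-stabilising solution. Libraries were made with the NEBNext Ultra II RNA kit, and paired-end reads of 150 bases were sequenced on an Illumina NovaSeq instrument. The general protocol text mentions ligation for 4 h or 5 h, while the titles and the series' design give 4 h. A left lung comes from 1 animal, so the 3 lungs of a group were taken as 3 mice. The naive mice were not described as operated on, so operation and ischemia were not separated.

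The authors deposited 1 table of 23194 genes with Ensembl identifiers, symbols, coordinates and gene lengths. Per the file headers, it holds read counts per gene, normalized counts, FPKM values, and the authors' log2 fold changes with p-values and adjusted p-values for the comparison of the groups. The submitters' processing notes name STAR, HTSeq, DESeq2, edgeR and STAR-Fusion with the mouse build mm10. Versions, settings and the strand setting of the counting are not given in the sources used here. Every deposited count is a whole number. The authors' deposited signal, the normalized counts, equalled the counts divided by 1 factor per library within a relative tolerance of 1e-06. The deposited FPKM values were recovered from the counts, the gene lengths and the column totals within the same tolerance, so the totals cover the whole table. Of the identifiers, 98.9% were in GENCODE M21, and 99.9% of these overlapped the coordinates of that annotation. Coordinates are printed as the table gives them.

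Counts were analysed as deposited, with no per-library value column left unused. Genes were kept by edgeR's filterByExpr for the groups, which left 15486 genes. Library sizes were scaled by TMM, and group means were compared with edgeR's robust quasi-likelihood F test (edgeR 4.0.16, limma 3.58.1, R 4.3.3) with group as the only term. Tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method over all genes tested. A gene was called changed at an adjusted p under 0.05, and log2 fold changes are injured over naive with their standard errors. CPM values are counts scaled to the TMM-adjusted library size and are given as mean ± SD of 3 mice.

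Before the data were examined, 42 gene lists of lung cell types, injury responses and contaminating tissues were fixed. Of their 833 symbols, 21 were absent from the table and counted as not measured. Each of the 41 lists with 5 or more tested members was compared with all other genes by camera on log2 CPM values with an inter-gene correlation of 0.01, adjusted over the lists. The alternatives were camera with an estimated correlation and fry, which asks whether the members move on balance in 1 direction. The text names genes by a rule fixed at the same time. The rule takes the 8 largest rises and 8 largest falls among called genes with a mean of 10 CPM or more in the higher group and no overlap between groups, leaving out predicted genes and antigen receptor segments. For each list it takes the 3 called members with the largest changes in the prevailing direction at 1 CPM or more and the 1 called member with the largest opposite change, or the 2 most abundant members where none was called. Il6, Tnf, Cxcl1, Ccl2, Hmox1, Sftpc, Ager, Pecam1, Cdh5 and Scgb1a1 were always included. Genes named outside this rule are said to be so.

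The alternatives were DESeq2's size factors, library size alone, no filter on low counts, a filter of 1 CPM in 3 samples, DESeq2 1.42.0, limma-voom, leaving out the 20 most abundant genes and haemoglobin genes, the replicate number as a block, offsets for gene length, and each of the 6 libraries left out in turn. A fit with a clock score per library as a covariate was added after the data were seen. The procedure was tested on counts simulated in a single draw, with the means, edgeR's dispersions and library sizes of these samples. In these counts 200 of 15486 genes were changed. These 200 were drawn from genes with a mean above 1 CPM, so recovery of less abundant genes was not tested. For this comparison edgeR recovered 81 of 100 genes changed by a log2 fold of 1 and 97 of 100 changed by a log2 fold of 2, among 15351 genes tested. Of its 198 calls, 20 were false (10.1%), above the nominal 5%, so single genes close to the threshold are less secure than their adjusted p states. DESeq2 made 47 false calls among 231 (20.3%). Camera called the 1 list that was changed and 0 of 40 lists that were not. The simulated genes varied independently, so this does not test camera on lists whose members vary together. In the data the estimated correlation reached 0.951, for heart muscle markers.

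Total counts per library ran from 18913487 to 34986276. The common biological coefficient of variation was 16.5%, and the median standard error of a log2 fold change was 0.142. Ratios of summed counts are scaled by the groups' total counts and carry exact Clopper-Pearson 95% intervals, which cover counting error only. Library properties were compared by exact two-sided permutation tests, whose smallest possible p with 3 against 3 is 0.1. Because no strand setting is given, reads of overlapping and antisense genes cannot be told apart. Counts of near-identical genes are uncertain, among them the Saa, Serpina3, Hba-a and Ly6c genes. Transcript isoforms and fusions were not analysed here.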

Results

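RNA was profiled from 6 whole left lungs of mice, 3 naive and 3 taken after 4 h of left pulmonary artery ligation and 24 h of reperfusion, here called injured lungs. Naive lungs held 29572273, 18913487 and 34986276 gene counts in replicates 1 to 3, and injured lungs held 20062818, 22432227 and 23638078. In all 6 libraries the most abundant transcript was Scgb1a1, which encodes the main secretory protein of club cells. The 20 most abundant genes took 11.1% ± 0.323 (SD, n = 3) of the counts in naive and 10.8% ± 0.164 (SD, n = 3) in injured lungs. Total counts, this share and the mitochondrial and haemoglobin shares were compared between groups by exact two-sided permutation tests, which cannot reach a p under 0.05 with 3 against 3. Their p ran from 0.3 to 0.9 where 0.1 is the smallest possible. Transcripts of the Y chromosome gene Ddx3y were present at 77.8 ± 12.0 CPM in naive and 71.5 ± 6.00 CPM in injured lungs. The first principal component held 42.5% of the variance and separated the groups, while the second held 23.7% and spread the lungs within both groups. On the second, naive replicates 1, 2 and 3 lay at 19.8, -3.63 and -17.1, and injured replicates 1, 2 and 3 at 11.1, 25.2 and -35.4.

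The comparison asked which transcripts differed after warm ischemia and reperfusion. Values in parentheses are edgeR's log2 fold changes of injured over naive lungs ± SE, with adjusted p. Saa3, an acute phase serum amyloid, rose from 1.75 ± 0.818 to 342 ± 69.2 CPM (log2 fold 7.56 ± 0.33, adjusted p = 0.000165). Arg1, the arginine-degrading enzyme of alternatively activated macrophages, rose from 2.37 ± 0.405 to 85.3 ± 30.2 CPM (log2 fold 5.19 ± 0.31, adjusted p = 0.000596). Timp1, an inhibitor of matrix metalloproteinases, rose from 5.43 ± 1.46 to 124 ± 46.9 CPM (log2 fold 4.52 ± 0.36, adjusted p = 0.00435). Among the falls, Sfrp2, a secreted modulator of Wnt signalling, went from 12.7 ± 3.29 to 3.09 ± 1.03 CPM (log2 fold -2.03 ± 0.28, adjusted p = 0.00629). Fmod, a collagen-binding proteoglycan, went from 17.1 ± 1.63 to 4.85 ± 1.05 CPM (log2 fold -1.82 ± 0.18, adjusted p = 0.000967).

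Of 15486 genes tested by edgeR, 482 were called at an adjusted p under 0.05, of which 334 were higher and 148 lower in injured lungs. The change was at least 2-fold for 172 of the higher and 40 of the lower genes. Under the naming rule, which asks for 10 CPM or more in the higher group and no overlap between groups, the other genes with the largest rises were Saa1, Chl1, S100a8, S100a9 and Retnlg. Saa1 had 3 counts in the naive and 1529 in the injured libraries. Scaled by the groups' total counts, the ratio of summed counts was 643 with a 95% counting interval of 219.7 to 3123. Chl1, a neural cell adhesion molecule, was called higher (log2 fold 5.33 ± 0.87, adjusted p = 0.0464), with 37.9 CPM in injured replicate 3 against 10.6 and 8.68 CPM in injured replicates 1 and 2. By the same rule the other genes with the largest falls were Colq, Scube2, Fras1, Ctgf, Ccl22 and Abi3bp, with log2 fold changes from -1.56 for Colq to -1.16 for Abi3bp. Ctgf, a matricellular protein induced by mechanical stress, fell from 194 ± 19.1 to 75.6 ± 19.3 CPM (log2 fold -1.36 ± 0.18, adjusted p = 0.00673). Abi3bp, an extracellular matrix protein, fell from 112 ± 3.92 to 49.9 ± 5.65 CPM (log2 fold -1.16 ± 0.10, adjusted p = 0.000460). In the table's mm10 coordinates Saa3 (ENSMUSG00000040026, chromosome 7, 46711998 to 46715676), Arg1 (ENSMUSG00000019987, chromosome 10, 24915208 to 24927470) and Timp1 (ENSMUSG00000001131, chromosome X, 20870166 to 20874735) marked the rises. Among the falls lay Sfrp2 (ENSMUSG00000027996, chromosome 3, 83766321 to 83774316), Fmod (ENSMUSG00000041559, chromosome 1, 134037254 to 134048277), Ctgf (ENSMUSG00000019997, chromosome 10, 24595442 to 24598683) and Abi3bp (ENSMUSG00000035258, chromosome 16, 56477846 to 56690128). The numbers of higher and lower genes were 217 and 131 without naive replicate 1 and 145 and 50 without naive replicate 2. They were 172 and 48 without injured replicate 1, and 247 and 88 without injured replicate 2. Of the 16 genes under this rule, calls were lost for Saa1 without naive replicate 1 or 3 (adjusted p up to 0.0611), Chl1 without naive replicate 1, 2 or 3 or injured replicate 1 (adjusted p up to 0.192), Retnlg without naive replicate 1, 2 or 3 or injured replicate 1 (adjusted p up to 0.104), S100a8 without naive replicate 1 or 3 or injured replicate 1 or 2 (adjusted p up to 0.107) and S100a9 without naive replicate 3 (adjusted p up to 0.0554). They were also lost for Colq without naive replicate 2 or injured replicate 1 or 2 (adjusted p up to 0.113), Fras1 without naive replicate 2 or 3 or injured replicate 1 or 3 (adjusted p up to 0.181) and Ccl22 without naive replicate 2 or injured replicate 1 (adjusted p up to 0.0572). The log2 fold change of Chl1 was 4.35 without injured replicate 3. That of Saa1 was 9.10 with all libraries, 9.76 without naive replicate 3 and 8.44 without injured replicate 3.

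**Figure D1:**
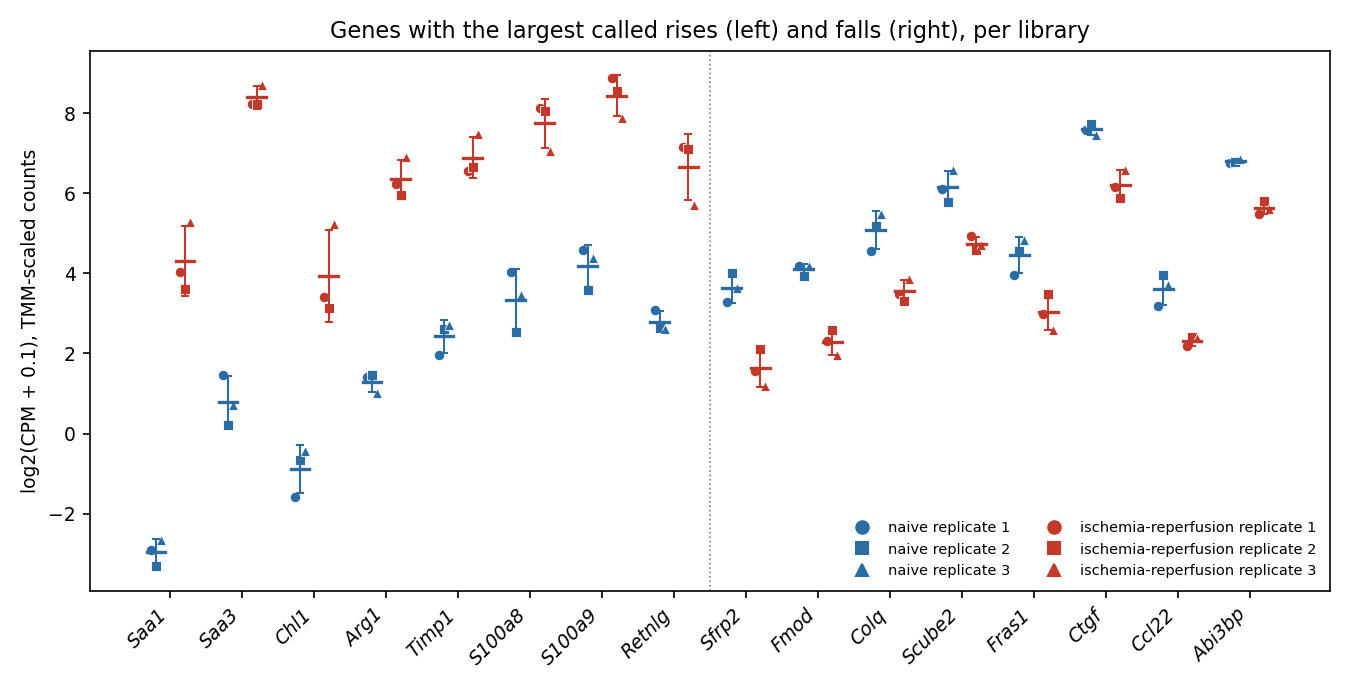
Each point is 1 library's level as log2(CPM + 0.1) for the 8 genes with the largest rises and the 8 with the largest falls under the naming rule, with bars at the mean and SD of 3 naive (blue) or 3 injured (red) lungs. The groups do not overlap for any of these genes, as the naming rule required, and Saa3 lies at 302, 303 and 422 CPM in the injured lungs.

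Neutrophil transcripts formed the group with the most rises. Of 20 tested neutrophil markers, 15 rose and 0 fell over all genes tested, with a median log2 fold change of 3.29. The count was 17 higher and 0 lower adjusted over the list alone. Ly6g, a surface antigen of mouse neutrophils, rose from 0.155 ± 0.121 to 5.15 ± 2.55 CPM (log2 fold 4.91 ± 0.62, adjusted p = 0.00518). S100a8 and S100a9, the subunits of calprotectin, also rose. S100a8 went from 11.02 ± 5.39 to 227 ± 81.5 CPM (log2 fold 4.34 ± 0.54, adjusted p = 0.0243) and S100a9 from 18.9 ± 6.29 to 363 ± 118 CPM (log2 fold 4.25 ± 0.40, adjusted p = 0.00788). As a list, neutrophil markers ranked higher than other genes (camera adjusted p = 3.87e-30, adjusted p = 0.0657 with an estimated correlation). Without naive replicate 3 the log2 fold change of Ly6g was 5.86. The mean level of the list, relative to naive lungs, was 3.50, 2.99 and 2.83 log2 units in injured replicates 1, 2 and 3. S100a8 lost its call without naive replicate 1, naive replicate 3, injured replicate 1 or injured replicate 2, with adjusted p up to 0.107. S100a9 lost it without naive replicate 3, with adjusted p = 0.0554.

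Acute phase and antimicrobial genes included 7 rises and 0 falls among 20 tested members, and 12 rises and 0 falls adjusted over the list alone. Besides Saa3 and Saa1, Saa2 rose (log2 fold 5.89 ± 1.09, adjusted p = 0.0334) from 5 counts over the naive to 260 over the injured libraries. Saa1 and Saa2 are near-identical copies, so their counts are uncertain one against the other. The list ranked higher than other genes (camera adjusted p = 5.79e-12, adjusted p = 0.232 with an estimated correlation). Of 29 tested cytokines and chemokines, out of 32 listed, 5 rose and 1 fell, and 13 rose and 1 fell adjusted over the list alone. Camera placed the list higher (camera adjusted p = 3.51e-05, adjusted p = 0.337 with an estimated correlation). The neutrophil chemoattractants Cxcl2 (log2 fold 6.21 ± 0.97, adjusted p = 0.0229) and Cxcl1 (log2 fold 2.90 ± 0.53, adjusted p = 0.0198) rose. The monocyte chemoattractant Ccl2 rose as well (log2 fold 3.10 ± 0.57, adjusted p = 0.0296), whereas Ccl22, a chemokine made by dendritic cells, fell (log2 fold -1.34 ± 0.21, adjusted p = 0.0105). Tnf missed the threshold (log2 fold 1.82 ± 0.43, adjusted p = 0.0544). Il6, with 6 counts over the naive and 56 over the injured libraries, was removed by the filter on low counts before this fit. Acute phase rises numbered 4 without naive replicate 1 or 3, with 1 fall without injured replicate 3. Cytokine rises numbered 1 without naive replicate 1, 0 without naive replicate 2 or 3, 2 without injured replicate 1 and 10 without injured replicate 2, and falls 0 without naive replicate 2 or injured replicate 1 and 2 without injured replicate 3. Other fits gave 13 by DESeq2, 2 by limma-voom, 10 with the replicate block and 0 with the clock score for cytokine rises. The log2 fold change of Saa2 was 7.20 without naive replicate 3 and 4.72 without injured replicate 3 and that of Cxcl2 was 6.93 without naive replicate 1 and 5.60 without injured replicate 1. That of Ccl2 was 2.43 without injured replicate 3. With 1 library left out, calls were lost for Saa1 without naive replicate 1 or 3 (adjusted p up to 0.0611), Saa2 without naive replicate 1, 2 or 3 or injured replicate 1 (adjusted p up to 0.148) and Cxcl1 without naive replicate 1, 2 or 3 or injured replicate 1 (adjusted p up to 0.0912). Also lost were the calls of Ccl2 without naive replicate 1, 2 or 3 or injured replicate 1 (adjusted p up to 0.142), Cxcl2 without naive replicate 1, 2 or 3 or injured replicate 3 (adjusted p up to 0.125) and Ccl22 without naive replicate 2 or injured replicate 1 (adjusted p up to 0.0572).

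Some monocyte and interstitial macrophage transcripts also rose. Of 22 tested members, 12 rose and 0 fell, and 17 rose and 0 fell adjusted over the list alone. Arg1 led this list, followed by Vcan, a large matrix proteoglycan (log2 fold 2.00 ± 0.31, adjusted p = 0.0241), and Trem2, a lipid-sensing macrophage receptor (log2 fold 1.45 ± 0.24, adjusted p = 0.0116). The list ranked higher than other genes (camera adjusted p = 7.36e-16, adjusted p = 0.0657 with an estimated correlation). Among 17 tested alveolar macrophage markers, 1 rose, Chil3, a chitinase-like secreted protein, from 733 ± 126 to 1227 ± 70.2 CPM (log2 fold 0.74 ± 0.13, adjusted p = 0.0161). None of the others passed the test, 2 rose adjusted over the list alone, and the median was 0.00090. Complement genes included 6 rises and 1 fall among 20 tested members, and 8 rises and 1 fall adjusted over the list alone (camera adjusted p = 0.00166, adjusted p = 0.389 with an estimated correlation). The rises were led by the anaphylatoxin receptors C5ar1 (log2 fold 1.25 ± 0.12, adjusted p = 0.000892) and C3ar1 (log2 fold 1.16 ± 0.24, adjusted p = 0.0330) and by Cfp, or properdin (log2 fold 0.93 ± 0.13, adjusted p = 0.00649), which are also expressed by phagocytes. C2, a component of the classical pathway, fell (log2 fold -1.34 ± 0.30, adjusted p = 0.0475). Monocyte and macrophage rises numbered 5 without naive replicate 1, 6 without naive replicate 2 and 7 without naive replicate 3. Complement rises numbered 2 without naive replicate 1 or injured replicate 2 and 3 without naive replicate 2 or 3. Alveolar macrophage rises numbered 0 without naive replicate 1 or injured replicate 1 or 2 and 2 without injured replicate 3, with 1 fall without injured replicate 2. With the clock score as a covariate, monocyte and macrophage rises numbered 5 and complement rises 2. The fall of C2 was not called there, with library size alone or with the replicate block. By DESeq2, 3 alveolar macrophage markers rose. Fits leaving out 1 library lost the calls of Vcan without naive replicate 1, 2 or 3 (adjusted p up to 0.126), Trem2 without injured replicate 1 (adjusted p up to 0.0588) and Chil3 without naive replicate 1 or injured replicate 1 or 2 (adjusted p up to 0.0698). Calls were also lost for C3ar1 without any 1 library except injured replicate 1 (adjusted p up to 0.141) and C2 without any 1 library except injured replicate 2 (adjusted p up to 0.170).

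Some T cell and MHC class II transcripts were lower. Among 20 tested T cell markers, 4 fell and 0 rose, and 18 fell and 0 rose adjusted over the list alone, with a median of -0.70. Lef1, a transcription factor of naive T cells, fell from 15.9 ± 2.22 to 7.66 ± 0.569 CPM (log2 fold -1.05 ± 0.15, adjusted p = 0.00672). The co-receptor gene Cd4 (log2 fold -0.94 ± 0.21, adjusted p = 0.0432) and the receptor signalling chain Cd247 (log2 fold -0.85 ± 0.19, adjusted p = 0.0403) were also called lower. The list ranked lower than other genes (camera adjusted p = 1.82e-14, adjusted p = 0.0657 with an estimated correlation). Among 18 tested dendritic cell markers, 4 fell and 0 rose, and 11 fell and 0 rose adjusted over the list alone (camera adjusted p = 6.04e-09, adjusted p = 0.0657 with an estimated correlation). The members called were MHC class II genes, which other antigen-presenting cells also express, led by Cd74, the invariant chain. Cd74 fell from 1237 ± 44.6 to 819 ± 15.7 CPM (log2 fold -0.60 ± 0.089, adjusted p = 0.00788), followed by H2-Aa (log2 fold -0.59 ± 0.11, adjusted p = 0.0198) and H2-Eb1 (log2 fold -0.58 ± 0.10, adjusted p = 0.0184). None of 12 tested B cell markers passed the test and 1 fell adjusted over the list alone. Camera placed them lower (camera adjusted p = 8.03e-05, adjusted p = 0.390 with an estimated correlation). Cd79a and Cd79b, the signalling chains of the B cell receptor, had log2 fold changes of -0.25 ± 0.14 and -0.20 ± 0.10. None of 14 NK and cytotoxic cell markers passed the test, with or without adjustment over the list alone. Camera placed them lower (camera adjusted p = 0.0131, adjusted p = 0.632 with an estimated correlation), with Il2rb at -0.28 ± 0.20 and Gzma at -0.37 ± 0.21. None of 5 tested eosinophil, mast cell and basophil markers, out of 13 listed, passed it either, nor adjusted over the list alone, with Gata2 at 0.16 ± 0.15 and Hdc at 0.44 ± 0.14. At an unadjusted p under 0.05 there were 7 B cell, 1 NK and 1 eosinophil, mast cell and basophil markers. DESeq2 called 1 B cell marker lower, 0 NK markers and 1 marker of the last list higher, while limma-voom called 0. With no filter on low counts edgeR called 1 B cell marker lower and 1 marker of the last list higher. T cell falls numbered 2 without naive replicate 1 or 2 or injured replicate 1 or 3. Dendritic cell falls numbered 2 without naive replicate 1 and 1 without naive replicate 2 or injured replicate 1. In other fits T cell falls numbered 9 with no filter, 11 by DESeq2, 7 with length offsets and 2 with the clock score, and dendritic cell falls 9 with no filter and 10 by DESeq2. B cell falls numbered 3 without naive replicate 3 and 1 without injured replicate 3, and rises of eosinophil, mast cell and basophil markers 1 without naive replicate 3 or injured replicate 2. Calls were lost for Cd4 without any 1 library except injured replicate 2 (adjusted p up to 0.159) and Cd247 without any 1 library (adjusted p up to 0.172). Also lost were the calls of H2-Aa without naive replicate 1 or 2 or injured replicate 1 (adjusted p up to 0.0935) and H2-Eb1 without naive replicate 1 or 2 or injured replicate 1 (adjusted p up to 0.0919). The camera call of NK markers was lost without naive replicate 3 or injured replicate 3, at an adjusted p up to 0.266.

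**Figure D2:**
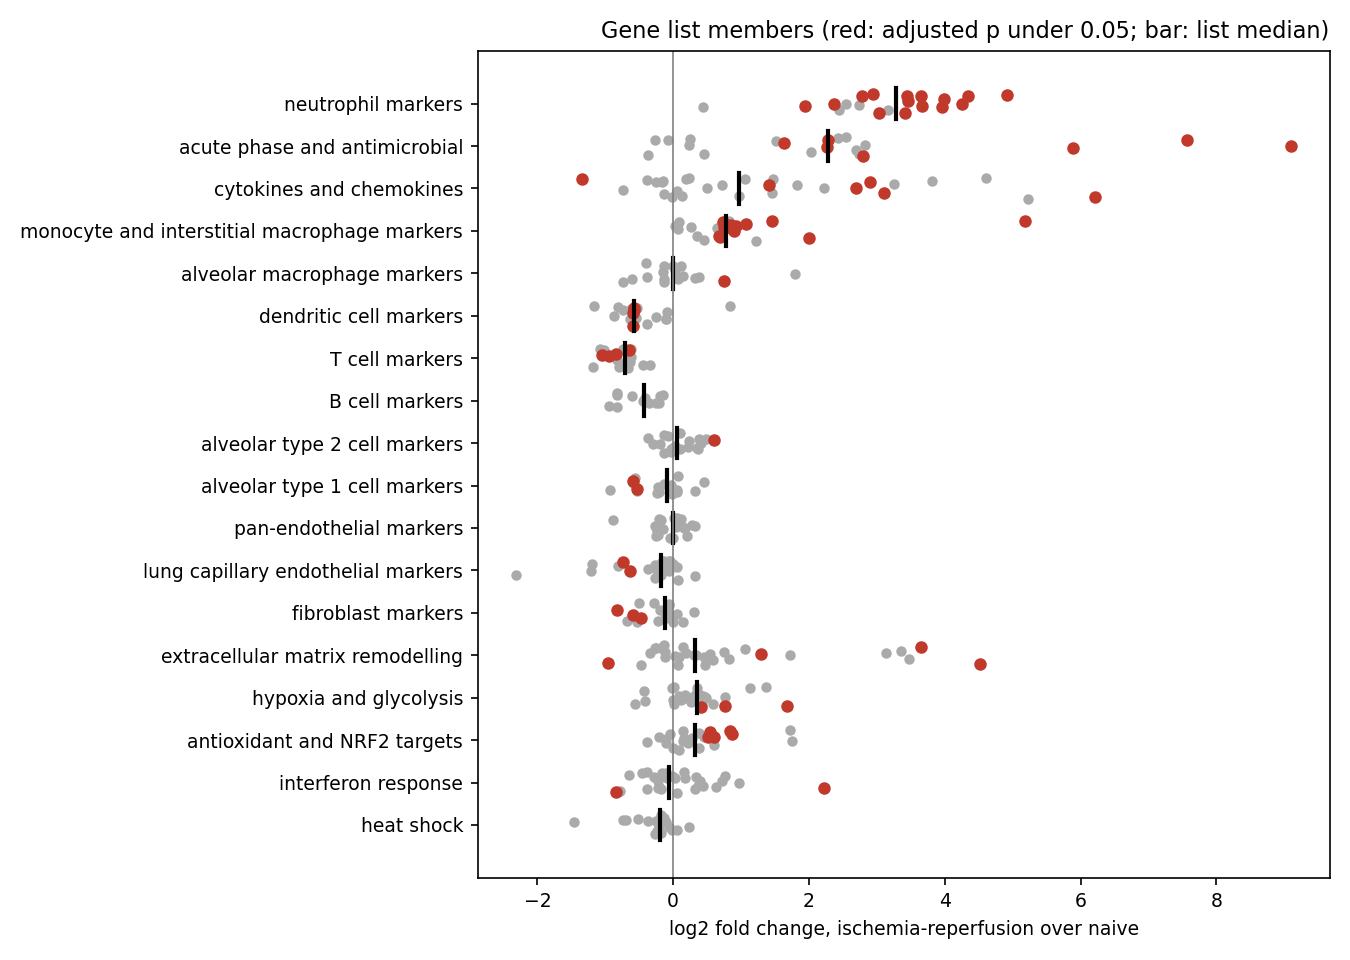
Each point is 1 tested member of a gene list, placed by its log2 fold change of injured over naive lungs, with red points for an adjusted p under 0.05 in edgeR and black bars at list medians. Among the lists shown, medians run from 3.29 for neutrophil markers to -0.70 for T cell markers, and that of pan-endothelial markers is -0.0057.

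Most epithelial markers did not pass the test. Among 20 tested alveolar type 2 cell markers, 1 rose, Ctsh, a lysosomal protease that processes surfactant protein B, from 305 ± 33.0 to 464 ± 19.4 CPM (log2 fold 0.61 ± 0.10, adjusted p = 0.0132). The count was 4 adjusted over the list alone. Sftpc, encoding surfactant protein C, stood at 15756 ± 1021 CPM in naive and 14305 ± 643 CPM in injured lungs (adjusted p = 0.602). Among 20 tested alveolar type 1 cell markers 2 fell. They were the basement membrane collagen Col4a3 (log2 fold -0.59 ± 0.11, adjusted p = 0.0228) and the tight junction gene Cldn18 (log2 fold -0.53 ± 0.11, adjusted p = 0.0325). Adjusted over the list alone, 4 fell and 1 rose (camera adjusted p = 0.00839, adjusted p = 0.632 with an estimated correlation). Ager, a membrane receptor abundant in type 1 cells, had a log2 fold change of -0.053 ± 0.12 (adjusted p = 0.882). In the list of transitional alveolar epithelium, 1 of 18 tested members rose, the galectin Lgals3 (log2 fold 0.69 ± 0.096, adjusted p = 0.00635), which macrophages also express. Ctgf and the growth factor gene Areg (log2 fold -1.92 ± 0.33, adjusted p = 0.0146) fell, and adjusted over the list alone 5 rose and 2 fell. Among 18 ciliated cell markers, 1 fell, Tppp3 (log2 fold -0.56 ± 0.12, adjusted p = 0.0312). Among 19 club and secretory cell markers, 1 rose, Cldn10 (log2 fold 0.72 ± 0.15, adjusted p = 0.0306). Both counts were the same adjusted over the list alone. Scgb1a1 stood at 23135 ± 6061 CPM in naive and 21225 ± 2751 CPM in injured lungs (adjusted p = 0.818). The club cell list had a positive median, 0.19, and a negative direction in camera (adjusted p = 0.775). Its mean level, relative to naive lungs, was -0.42, -0.45 and 0.71 log2 units in injured replicates 1, 2 and 3. Type 2 rises numbered 0 without naive replicate 2 or injured replicate 1 and 2 without naive replicate 3, with 1 fall without injured replicate 3. Type 1 falls numbered 1 without naive replicate 2 or injured replicate 3 and 0 without injured replicate 2. Transitional rises numbered 2 without naive replicate 3 or injured replicate 3 and falls 1 without injured replicate 1 or 2. Ciliated falls numbered 0 without naive replicate 1, 2 or 3 or injured replicate 1 or 2. Club cell rises numbered 0 without naive replicate 1, 2 or 3 or injured replicate 2, with 1 fall without naive replicate 3. In other fits type 2 rises numbered 3 by DESeq2 and 2 with the clock score. Type 1 falls were 4 with no filter, 5 by DESeq2 and 1 with length offsets, and type 1 rises 1 with library size alone, with no filter, by DESeq2 or with the clock score. Transitional rises were 4 with no filter or by DESeq2, 5 with the replicate block and 2 with the clock score, and falls 1 with the clock score. Club cell rises were 3 by DESeq2 or with the clock score and 0 with length offsets, and falls 1 by DESeq2 or with the replicate block. With 1 library left out, calls were lost for Ctsh without naive replicate 2 or injured replicate 1 (adjusted p up to 0.0744), Col4a3 without injured replicate 1 or 2 (adjusted p up to 0.0828) and Cldn18 without naive replicate 1 or 2 or injured replicate 2 or 3 (adjusted p up to 0.115). Calls were also lost for Areg without injured replicate 1 or 2 (adjusted p up to 0.0669), Tppp3 without any 1 library except injured replicate 3 (adjusted p up to 0.117) and Cldn10 without any 1 library except injured replicate 3 (adjusted p up to 0.138). The camera call of type 1 markers was lost without injured replicate 3, at an adjusted p of 0.199.

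None of 23 pan-endothelial markers passed the test, nor when adjusted over the list alone, while a few capillary genes fell. The junction genes Pecam1 (log2 fold -0.25 ± 0.097, adjusted p = 0.233) and Cdh5 (log2 fold -0.23 ± 0.11, adjusted p = 0.337) were not called, and nor were the most abundant members Calcrl (log2 fold 0.28 ± 0.12, adjusted p = 0.253) and Ptprb (log2 fold -0.041 ± 0.12, adjusted p = 0.911). Of the pan-endothelial list, 3 members had an unadjusted p under 0.05, DESeq2 and the replicate block each called 1 lower and limma-voom called 0. Among 21 tested lung capillary markers, the transcription factor gene Foxf1 fell from 390.3 ± 16.4 to 234 ± 46.6 CPM (log2 fold -0.74 ± 0.13, adjusted p = 0.0188), and so did Tmem100 (log2 fold -0.63 ± 0.11, adjusted p = 0.0161). The count was 2 lower, and 3 lower adjusted over the list alone (camera adjusted p = 0.000193, adjusted p = 0.156 with an estimated correlation). Of 10 lymphatic endothelial markers 1 fell, Sned1 (log2 fold -0.66 ± 0.10, adjusted p = 0.0103), and 3 rose and 2 fell adjusted over the list alone. In the list of endothelial activation, 2 of 19 tested members rose, namely the leukocyte adhesion receptor Selp (log2 fold 1.08 ± 0.24, adjusted p = 0.0427) and the protein C receptor Procr (log2 fold 1.01 ± 0.20, adjusted p = 0.0278). Thbd, encoding the anticoagulant thrombomodulin, fell from 1432 ± 182 to 939 ± 110.2 CPM (log2 fold -0.61 ± 0.13, adjusted p = 0.0331). Adjusted over the list alone, 4 rose and 3 fell. Among 22 tested coagulation and fibrinolysis genes, 4 rose and 1 fell, the fall being Thbd. These became 6 rises and 2 falls adjusted over the list alone (camera adjusted p = 0.0339, adjusted p = 0.468 with an estimated correlation). The rises included the plasminogen activator inhibitor gene Serpinb2 (log2 fold 4.25 ± 0.72, adjusted p = 0.0259), F13a1 (log2 fold 1.47 ± 0.22, adjusted p = 0.0182) and F10 (log2 fold 1.18 ± 0.13, adjusted p = 0.00167). Macrophages also express genes of this list, F13a1 and F10 among them. Pan-endothelial falls numbered 1 without naive replicate 1, and capillary falls 1 without naive replicate 1 and 0 without naive replicate 2 or injured replicate 2. Lymphatic rises numbered 1 without naive replicate 1 or injured replicate 3 and falls 2 without injured replicate 1 or 3. Rises of endothelial activation numbered 0 without naive replicate 1 or 2 or injured replicate 1 and 1 without naive replicate 3 and its falls 0 without naive replicate 2 or injured replicate 2. Coagulation rises numbered 1 without naive replicate 1 and 2 without naive replicate 2 or injured replicate 1 or 2, and falls 0 without naive replicate 2 or 3 or injured replicate 1 or 2 and 2 without injured replicate 3. In other fits capillary falls numbered 4 by DESeq2, and coagulation rises 2 with the clock score. Lymphatic rises were 1 with library size alone, with no filter, with the replicate block or with length offsets and 2 by DESeq2, and falls 2 by DESeq2. Endothelial activation rises were 4 with no filter, 5 by DESeq2 and 1 with the clock score, and its falls 2 with DESeq2's size factors, with no filter, with the filter of 1 CPM in 3 samples, without abundant genes or with length offsets, 4 by DESeq2 and 3 with the replicate block. The log2 fold change of Serpinb2 was 4.93 without naive replicate 1 and 3.50 without injured replicate 3. Fits leaving out 1 library lost the calls of Foxf1 without naive replicate 1 or 2 or injured replicate 2 (adjusted p up to 0.0640), Tmem100 without naive replicate 2 or injured replicate 2 (adjusted p up to 0.0693), Selp without any 1 library (adjusted p up to 0.138) and Procr without any 1 library except injured replicate 3 (adjusted p up to 0.120). Also lost were the calls of Thbd without naive replicate 2 or 3 or injured replicate 1 or 2 (adjusted p up to 0.139), Serpinb2 without naive replicate 1, 2 or 3 (adjusted p up to 0.126) and F13a1 without naive replicate 1 or injured replicate 1, 2 or 3 (adjusted p up to 0.0669). The camera call of coagulation genes was lost without naive replicate 2 or injured replicate 3, at an adjusted p up to 0.199.

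The calls among fibroblast and smooth muscle markers were falls, while matrix remodelling genes moved in both directions. Among 20 tested fibroblast markers, 3 fell and 0 rose, and 4 fell and 0 rose adjusted over the list alone (camera adjusted p = 0.00286, adjusted p = 0.156 with an estimated correlation). The basement membrane ligand Npnt fell from 1413 ± 339 to 797 ± 42.9 CPM (log2 fold -0.83 ± 0.16, adjusted p = 0.0253). The other falls were its receptor Itga8 (log2 fold -0.48 ± 0.10, adjusted p = 0.0354) and Col14a1 (log2 fold -0.60 ± 0.13, adjusted p = 0.0399). In extracellular matrix remodelling, 3 of 30 tested members rose and 1 fell, and 7 rose and 2 fell adjusted over the list alone (camera adjusted p = 0.000729, adjusted p = 0.632 with an estimated correlation). Timp1, the neutrophil collagenase Mmp8 (log2 fold 3.65 ± 0.29, adjusted p = 0.00149) and Tgfbi (log2 fold 1.29 ± 0.13, adjusted p = 0.000892) rose, and Postn, the matricellular protein periostin, fell from 572 ± 91.4 to 293 ± 23.5 CPM (log2 fold -0.96 ± 0.13, adjusted p = 0.00518). Of 17 smooth muscle and pericyte markers, 1 fell, the enteric actin gene Actg2 (log2 fold -0.82 ± 0.13, adjusted p = 0.0119). The falls numbered 2 adjusted over the list alone (camera adjusted p = 0.000165, adjusted p = 0.470 with an estimated correlation). The mean level of this list, relative to naive lungs, was -0.16, 0.18 and -0.014 log2 units in naive replicates 1, 2 and 3. It was -0.35, -0.41 and -0.10 in injured replicates 1, 2 and 3. Heart muscle markers were also lowest in injured replicates 1 and 2, and a shared source was not tested. None of 10 mesothelial markers passed the test, nor adjusted over the list alone, and camera placed them lower (camera adjusted p = 0.0160, adjusted p = 0.632 with an estimated correlation). Upk3b stood at 42.0, 76.5 and 11.4 CPM in injured replicates 1, 2 and 3, against 99.4, 134 and 95.9 CPM in naive replicates 1, 2 and 3. Its groups did not overlap, but it was not called (log2 fold -1.34 ± 0.71, adjusted p = 0.453). Msln had a log2 fold change of -0.68 ± 0.32. No mesothelial marker had an unadjusted p under 0.05, and DESeq2 and limma-voom called 0. Fibroblast falls numbered 0 without naive replicate 2 or injured replicate 1 or 3 and 1 without injured replicate 2. Matrix rises numbered 5 without naive replicate 3, and smooth muscle falls 2 without naive replicate 1, 0 without naive replicate 2 or injured replicate 1 and 3 without injured replicate 3. In other fits fibroblast falls numbered 1 with length offsets or with the clock score, and smooth muscle falls 2 by DESeq2. Matrix rises were 8 by DESeq2 and 9 with the replicate block, and matrix falls 2 with library size alone, with no filter, by DESeq2 or with the clock score. Calls were lost for Npnt without naive replicate 2 or injured replicate 1, 2 or 3 (adjusted p up to 0.119) and Itga8 without naive replicate 1 or 2 or injured replicate 1 or 3 (adjusted p up to 0.152). Calls were also lost for Col14a1 without any 1 library except naive replicate 1 (adjusted p up to 0.159) and Actg2 without naive replicate 2 or injured replicate 1 (adjusted p up to 0.0586). The camera call of mesothelial markers was lost without injured replicate 3 (adjusted p = 0.677). That of matrix genes was lost without naive replicate 1 or injured replicate 3 (adjusted p up to 0.0553).

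Glycolytic and antioxidant genes were among the other rises. Slc16a3, Fth1, Gsr, G6pdx, Ninj1 and Pycard, named here, are also expressed by neutrophils and macrophages, whose markers rose in the same lungs. Of 27 tested hypoxia and glycolysis genes, 3 rose and 0 fell, and 9 rose and 1 fell adjusted over the list alone (camera adjusted p = 1.46e-05, adjusted p = 0.156 with an estimated correlation). The lactate exporter gene Slc16a3 rose from 10.6 ± 0.712 to 34.1 ± 3.82 CPM (log2 fold 1.68 ± 0.12, adjusted p = 0.000165). The other rises were the glycolytic enzymes Eno1 (log2 fold 0.76 ± 0.14, adjusted p = 0.0198) and Gpi1 (log2 fold 0.40 ± 0.083, adjusted p = 0.0308). Among 24 antioxidant genes and targets of NRF2, a transcription factor of the oxidative stress response, 5 rose and 0 fell. Adjusted over the list alone, 9 rose and 1 fell (camera adjusted p = 1.58e-06, adjusted p = 0.325 with an estimated correlation). Glutathione reductase Gsr (log2 fold 0.87 ± 0.089, adjusted p = 0.00116), the ferritin heavy chain Fth1 from 1698 ± 72.5 to 3044 ± 223 CPM (log2 fold 0.84 ± 0.10, adjusted p = 0.00344) and glucose-6-phosphate dehydrogenase G6pdx (log2 fold 0.60 ± 0.086, adjusted p = 0.00690) led this list. Hmox1, the haem-degrading enzyme, was not called (log2 fold 1.72 ± 0.55, adjusted p = 0.226). It stood at 83.8, 82.2 and 263 CPM in injured replicates 1, 2 and 3 against 43.6 ± 1.54 CPM in naive lungs. Of 36 cell cycle genes, 2 rose, Rrm2 (log2 fold 1.26 ± 0.25, adjusted p = 0.0297) and Mcm5 (log2 fold 0.88 ± 0.16, adjusted p = 0.0204), which act in DNA synthesis. Adjusted over the list alone, 4 rose (camera adjusted p = 2.90e-08, adjusted p = 0.495 with an estimated correlation). Of 19 tested genes of lytic cell death and the inflammasome, 2 rose, Ninj1, which mediates membrane rupture (log2 fold 0.73 ± 0.11, adjusted p = 0.00690), and the adaptor Pycard (log2 fold 0.72 ± 0.16, adjusted p = 0.0482). The rises numbered 5 adjusted over the list alone (camera adjusted p = 1.77e-05, adjusted p = 0.156 with an estimated correlation). Hypoxia and glycolysis rises numbered 1 without injured replicate 1 and 6 without injured replicate 2, with 1 fall without injured replicate 1. Cell cycle rises numbered 0 without naive replicate 1 or 2 and 1 without naive replicate 3 or injured replicate 1 or 3. Rises of lytic cell death numbered 1 without naive replicate 2 or 3 or injured replicate 1, 2 or 3. In other fits hypoxia and glycolysis rises numbered 8 with no filter, 9 by DESeq2 and 6 with the replicate block, and falls 1 by DESeq2, with the replicate block or with the clock score. Antioxidant rises were 10 by DESeq2, and falls 1 with the replicate block or with the clock score. Cell cycle rises were 4 with no filter, by DESeq2 or with the replicate block and 1 by limma-voom or with the clock score, and rises of lytic cell death 1 with library size alone or with length offsets, 4 with no filter and 5 by DESeq2. With 1 library left out, calls were lost for Eno1 without naive replicate 1 or 3 or injured replicate 1 (adjusted p up to 0.0870), Gpi1 without any 1 library (adjusted p up to 0.123) and Rrm2 without naive replicate 1 or 2 or injured replicate 1 or 3 (adjusted p up to 0.141). Also lost were the calls of Mcm5 without naive replicate 1, 2 or 3 (adjusted p up to 0.0744) and Pycard without any 1 library (adjusted p up to 0.145).

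Interferon, heat shock and protein-folding genes showed few or no calls. In the interferon list, 1 of 30 members rose, the antiviral enzyme gene Oas3, from 2.15 ± 0.198 to 10.1 ± 0.641 CPM (log2 fold 2.23 ± 0.18, adjusted p = 0.000319). The GTPase gene Gbp3 was the 1 fall (log2 fold -0.84 ± 0.12, adjusted p = 0.00690). Adjusted over the list alone, there were 2 rises and 5 falls. That list had a negative median (-0.059) and direction in camera but a positive mean (0.081) and direction in fry, and neither test called it in 1 direction. It was 1 of 22 lists that fry called when either direction counted (fry adjusted p = 1.91e-05). Among 18 glucocorticoid response genes, 1 rose, Lcn2 (log2 fold 2.28 ± 0.39, adjusted p = 0.0482), which is also a neutrophil and epithelial antimicrobial protein. Klf9 fell (log2 fold -0.60 ± 0.12, adjusted p = 0.0288), and adjusted over the list alone there were 2 rises and 2 falls. Of 20 heat shock genes, 24 genes of the unfolded protein and integrated stress response and 25 p53 targets, edgeR called 0, also adjusted over the list alone. Hspa8 stood at 1243 ± 791 CPM in naive and 1050.1 ± 148 CPM in injured lungs. Its naive values were 605, 995 and 2128 CPM in replicates 1, 2 and 3. The mean level of the heat shock list, relative to naive lungs, was -0.50, -0.23 and 0.74 log2 units in the same replicates. Naive replicate 3 thus widened the naive spread against which this list was tested. The log2 fold change was -0.37 ± 0.25 for Hsp90ab1, -0.0090 ± 0.31 for Hspa5, -0.028 ± 0.17 for Calr, -0.55 ± 0.28 for Btg2 and 0.020 ± 0.088 for Ccng1. At an unadjusted p under 0.05 there were 0 heat shock genes, 5 genes of the unfolded protein and integrated stress response and 0 p53 targets. DESeq2 called 1 gene of the stress response list higher and 1 lower and 0 of the others, and limma-voom called 0. With the clock score as a covariate, a fit chosen after the data were seen, edgeR called 7 heat shock genes and 1 gene of the stress response list lower. The replicate block and the fit with no filter each called 1 gene of the stress response list higher. Without naive replicate 3 edgeR called 5 genes of the stress response list higher. Of 28 nuclear oxidative phosphorylation genes none passed the test, nor adjusted over the list alone. Camera placed them higher (camera adjusted p = 0.00134, adjusted p = 0.632 with an estimated correlation), with Atp5b at 0.11 ± 0.10 and Atp5a1 at 0.051 ± 0.093. Of 12 mitochondrially encoded transcripts none passed it either, nor adjusted over the list alone. At an unadjusted p under 0.05 there were 3 nuclear and 0 mitochondrial members, and DESeq2 and limma-voom called 0 of either. The log2 fold changes were -0.065 ± 0.12 for mt-Co1 and -0.10 ± 0.11 for mt-Cytb. Interferon falls numbered 2 without naive replicate 3. Glucocorticoid rises numbered 0 without naive replicate 1, 2 or 3 or injured replicate 1 and 2 without injured replicate 2 or 3 and falls 0 without naive replicate 1 or 3 or injured replicate 1 or 2. In other fits interferon falls numbered 2 with no filter, with the replicate block, with length offsets or with the clock score and 3 by DESeq2. Glucocorticoid rises were 0 with no filter or with the clock score, 4 by DESeq2 and 2 with the replicate block, and falls 2 by DESeq2 and 0 with the clock score. Fits leaving out 1 library lost the calls of Lcn2 without naive replicate 1, 2 or 3 or injured replicate 1 (adjusted p up to 0.189) and Klf9 without any 1 library except injured replicate 3 (adjusted p up to 0.113). The camera call of oxidative phosphorylation was lost without injured replicate 3 (adjusted p = 0.182).

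Markers of tissues that a dissected lung can carry along varied between single libraries. None of 10 red blood cell, 13 heart muscle, 5 skeletal muscle, 9 fat cell or 4 sex-linked transcripts passed the test, nor adjusted over their lists alone. At an unadjusted p under 0.05 there were 1 heart muscle, 1 sex-linked and 0 other members, and DESeq2 and limma-voom called 0. Haemoglobin transcripts took 0.0108% ± 0.0110 (SD, n = 3) of naive and 0.00887% ± 0.00392 (SD, n = 3) of injured counts. Hbb-bs and Hba-a1 had log2 fold changes of -0.35 ± 0.94 and -0.30 ± 1.01. The heart muscle genes Myh6 and Actc1 stood at 276 ± 102 CPM in naive and 167 ± 117 CPM in injured lungs and at 142 ± 36.0 CPM in naive and 68.8 ± 33.5 CPM in injured lungs. Camera placed heart muscle markers lower (camera adjusted p = 0.000350, adjusted p = 0.632 with an estimated correlation), as well as fat cell markers (camera adjusted p = 0.0325, adjusted p = 0.632 with an estimated correlation), represented by Cfd at -1.08 ± 1.24 and Cidec at -0.60 ± 0.34. The skeletal muscle genes Ckm and Tnnt3 stood at -1.07 ± 0.66 and -0.58 ± 0.43, and the Y-linked Eif2s3y at 0.26 ± 0.11. The mean level of heart muscle markers, relative to naive lungs, was -0.96, -2.28 and 0.31 log2 units in injured replicates 1, 2 and 3. Without injured replicate 3 edgeR called 3 heart muscle markers lower. The heart muscle call in camera was lost without injured replicate 2 (adjusted p = 0.0805). That of fat cell markers was lost without naive replicate 2, naive replicate 3, injured replicate 1 or injured replicate 2 (adjusted p up to 0.425).

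Clock transcripts split the naive group. Arntl, an activator of the circadian clock, stood at 4.20, 2.43 and 27.7 CPM in naive replicates 1, 2 and 3 and at 21.1, 15.6 and 20.2 CPM in injured replicates 1, 2 and 3. Dbp, a clock output gene, stood at 116, 215 and 23.8 CPM in the naive and at 28.0, 60.7 and 31.7 CPM in the injured lungs. Both were chosen after their values were seen. Of 18 tested clock genes edgeR called 0, and 2 fell adjusted over the list alone. At an unadjusted p under 0.05 there were 4, DESeq2 and the replicate block each called 4 lower and limma-voom called 0. DESeq2's size factors and the fit with no filter each gave 1 lower, and the clock score as a covariate 1 higher. Camera placed the list lower (camera adjusted p = 0.0106, adjusted p = 0.468 with an estimated correlation). Its most abundant members, Tef and Nr1d1, had log2 fold changes of -0.44 ± 0.40 and -0.76 ± 0.26. Without naive replicate 3 edgeR called 4 clock genes higher and 6 lower, and without injured replicate 2 it called 2 lower. The camera call was lost without naive replicate 2 (adjusted p = 0.0672).

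**Figure D3:**
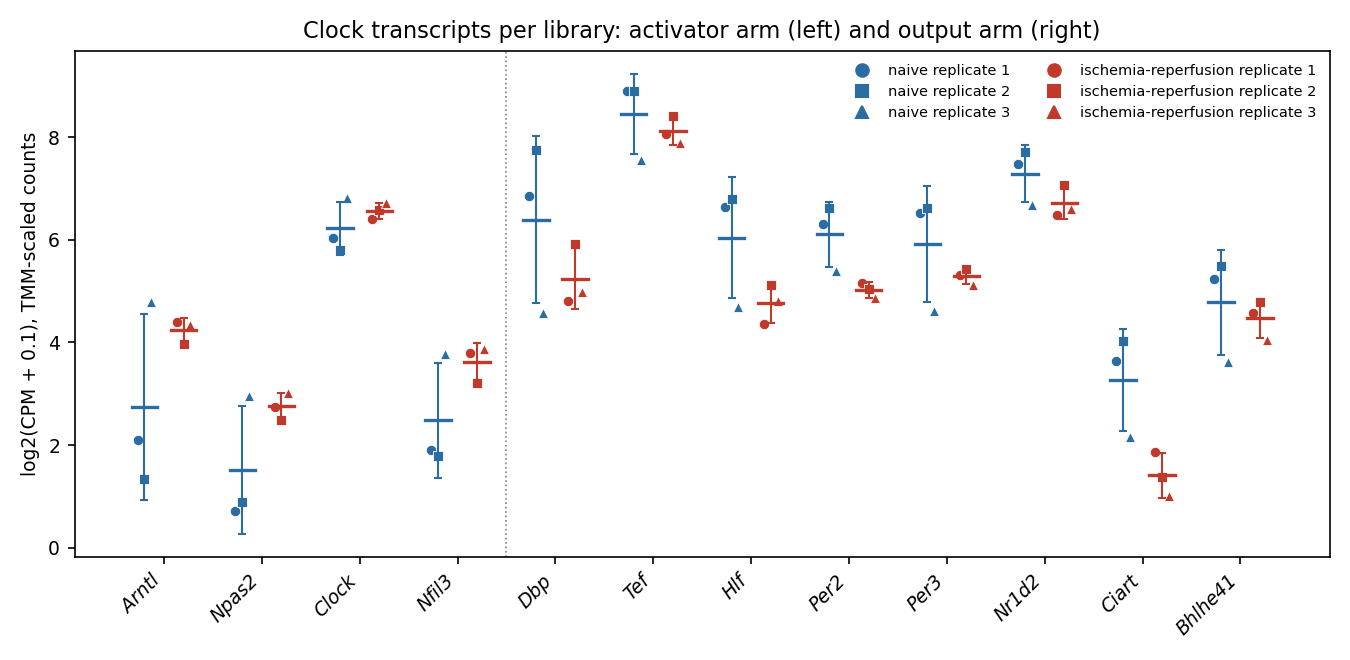
Each point is 1 library's level as log2(CPM + 0.1) for clock transcripts grouped after the data were seen into an activator and an output arm, with bars at the mean and SD of 3 naive (blue) or 3 injured (red) lungs. Naive replicate 3 lies beside the injured lungs, with Arntl at 27.7 CPM and Dbp at 23.8 CPM.

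The authors' deposited table gave an adjusted p for 15721 genes and called 967 of them at an adjusted p under 0.05, 568 higher and 399 lower in injured lungs. Of the 482 genes called here by edgeR, 479 were also called in the authors' deposited table, all in the same direction. Of the 3 genes not shared, 2 had no adjusted p there, among them Chl1, with an authors' log2 fold change of 0.858. In the authors' deposited table the log2 fold change of Saa3 was 3.28, that of Arg1 3.94 and that of Fmod -1.51, against 7.56, 5.19 and -1.82 by edgeR. The authors' values ran only from -1.67 to 3.94 over the whole table, while edgeR's reached 9.10. How the authors estimated them is not given, so their sizes cannot be set directly against those by edgeR.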

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

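The direction of every named gene called by edgeR held under the alternatives in which it could be tested. Of 71 named genes called, 24 were called under all 16 alternatives, the clock score covariate included, among them Saa3, Arg1, Timp1, Ly6g, Mmp8, Slc16a3, Gsr, Oas3, Sfrp2, Fmod, Abi3bp, Postn, Lef1 and Cd74. Fth1 was called under the 15 in which it was tested, being among the abundant genes left out in the other. The named genes lost 61 calls and gained 7 over the alternatives that kept all libraries, and lost 167 and gained 6 over those that left 1 out, which have fewer samples. DESeq2 called 578 higher and 398 lower genes, 81 of the latter at least 2-fold, and 178 list members against 91. In the simulation, a single draw with edgeR's dispersions, DESeq2 made more false calls than edgeR. That does not show how many of its added calls in these lungs are false. With no filter on low counts 269 genes were lower, where more genes were tested. With the clock score as a covariate, an alternative chosen after seeing the data, 279 genes were higher and 239 lower, and 306 genes were shared with the 482 called without it, and the cause was not tested. Camera called 24 lists, 12 higher and 12 lower, but 0 with an estimated correlation, where the smallest adjusted p was 0.0657 and 8 lists had an unadjusted p under 0.05. Fry called 7 lists in 1 direction and 22 when either direction counted. Leaving out 1 library gave 145 to 333 higher and 48 to 146 lower genes, 98 to 187 and 16 to 47 of them at least 2-fold, 50 to 100 list members and 19 to 26 lists by camera, with the fewest genes without naive replicate 2 or injured replicate 1.

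The labels do not say whether the replicate numbers pair the lungs. The correlations of deviations between lungs of the same number were 0.077, -0.085 and 0.15. Not every library correlated best with its own number. With 3 lungs in each group these values cannot decide whether the lungs were paired. With the replicate block, 413 genes were higher and 208 lower, 196 and 52 of them at least 2-fold, 125 list members and 24 lists were called. Of the 621 genes called with the block, 437 were shared with the fit without it. In the simulation the block made 37 false calls among 218, against 20 among 198 without it. The simulation held no pair effect, so it does not show how the block performs on paired lungs. The other scalings, filters, limma-voom, the removal of abundant genes and the length offsets kept all 4 counts within 1.5 times, apart from the filter named above, and no scaling moved the median log2 fold change of all genes beyond 0.0136. The low-value filter and pseudocount alternatives for tables without counts did not apply. Depth limited low transcripts such as Il6, which was filtered out.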

Other observations

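Several further groups of genes were put together after the data were seen, so their counts describe these libraries and are no independent evidence. Of 13 chemoattractant receptors of phagocytes, 9 rose and 0 fell, among them the chemokine receptors Ccr1 (log2 fold 1.99 ± 0.12, adjusted p = 8.15e-05) and Cxcr2 (log2 fold 3.45 ± 0.36, adjusted p = 0.00745) and the leukotriene receptor Ltb4r1 (log2 fold 1.42 ± 0.18, adjusted p = 0.00469). Of 6 Fc receptors and their adaptors, 4 rose, including Fcgr4 (log2 fold 1.48 ± 0.14, adjusted p = 0.000830), Fcer1g (log2 fold 0.90 ± 0.13, adjusted p = 0.00629) and Tyrobp (log2 fold 0.88 ± 0.10, adjusted p = 0.00243). Of 11 MHC class II genes, 5 fell and 0 rose.

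Other groups chosen in the same way hold basement membrane and matrix genes. Of 19 basement membrane and Fraser complex genes, 7 fell and 1 rose, the rise being the laminin chain Lamc3 (log2 fold 0.80 ± 0.088, adjusted p = 0.00191). Of 15 small leucine-rich proteoglycans and fibulins, 4 fell, among them Fbln5 (log2 fold -0.95 ± 0.13, adjusted p = 0.00649), Ecm2 (log2 fold -0.79 ± 0.13, adjusted p = 0.0108) and Prelp (log2 fold -0.66 ± 0.11, adjusted p = 0.0113). Cyp1a1, the classical target of the aryl hydrocarbon receptor, fell from 9.75 ± 4.30 to 1.46 ± 0.232 CPM (log2 fold -2.75 ± 0.37, adjusted p = 0.00629), the 1 call among 5 such targets. The epithelial junction gene Gjb5 (log2 fold 2.97 ± 0.36, adjusted p = 0.00321) and the basal keratin Krt14 (log2 fold 4.26 ± 0.68, adjusted p = 0.0184) were higher in each injured lung than in any naive lung. Krt5, the usual partner of Krt14, had 2, 0 and 55 counts in injured replicates 1 to 3 and was removed by the filter on low counts. The heat shock gene Hspa1b stood at 79.5 CPM in naive replicate 3, against 7.50 and 9.47 CPM in naive replicates 1 and 2.

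All tests in the following paragraphs were chosen after the results were seen. The call of 482 genes was compared with the other ways of dividing the 6 libraries into 3 and 3. Only the real grouping, 1 of 10 splits, gave as many genes, and the highest of the others gave 1, but 10 splits are too few for a share under 0.05.

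Neutrophil markers were higher in injured lungs by 3.11 ± 0.24 log2 units (difference of list means ± SE). More blood left in the injured lungs would raise red blood cell transcripts with them, and these changed by 0.46 ± 0.74 on average. Their median log2 fold change was -0.068, with 6 of 10 members below 0, so the sign of their change is uncertain. The neutrophil change exceeded the mean red blood cell change by 2.65 ± 0.70, which argues against a larger volume of residual blood as the whole cause. A smaller part stays open. Red blood cell transcripts do not show how many neutrophils the blood held, so neutrophils in blood and in lung tissue were not told apart. The red blood cell score also varied widely among naive lungs, at -0.093, -1.17 and 1.26 log2 units in replicates 1, 2 and 3. Anaesthesia and opening of the chest could also raise neutrophil markers without ischemia, and with 0 sham-operated libraries they cannot be told apart from ischemia-reperfusion. Recruitment of neutrophils by ischemia-reperfusion remains a hypothesis beside these.

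T cell markers were lower in injured lungs by a median log2 fold change of -0.70. Dilution of resident RNA by incoming cells would lower other resident markers alike. The change of pan-endothelial markers exceeded that of T cell markers by 0.70 ± 0.098 log2 units, and that of alveolar type 2 markers by 0.85 ± 0.13. Some other lists did fall, with mean changes of -0.46 ± 0.046 for dendritic cell, -0.39 ± 0.071 for lung capillary and -0.21 ± 0.058 for fibroblast markers. Smooth muscle markers changed by -0.29 ± 0.14, type 1 by -0.20 ± 0.12, club cell by -0.053 ± 0.43 and ciliated by -0.0038 ± 0.16. On this scale T cell markers changed by -0.75 ± 0.066. These values argue against dilution as the whole cause, while a part of it stays open. Lymphoid tissue carried along with the naive lungs might contribute T and B cells together. The B cell change exceeded the T cell change by 0.27 ± 0.17, less than 2 standard errors, while 5 lymphoid stroma genes grouped after the data were seen had a mean change of 0.19 ± 0.19 but a median log2 fold change of -0.17, so this stays open. A loss of T cells or of their transcripts after ischemia-reperfusion is a further hypothesis, and no cell counts were analysed here.

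Clock transcripts set naive replicate 3 apart from naive replicates 1 and 2, and its score, the output arm minus the activator arm, differed from their mean by -3.71 log2 units, while those replicates differed by 0.53. As the arms were grouped after these values were seen, the score restates the pattern and does not test another hour of tissue collection, which stays open. For the same reason its difference from the highest injured library, -1.01, does not test ischemia-reperfusion as the only source of the clock difference between groups, and an effect of injury on the clock stays open. With the clock score as a covariate, rises called numbered 10 neutrophil, 5 monocyte and macrophage, 6 acute phase and 0 cytokine genes, against 15, 12, 7 and 5 without it, and falls 2 T cell and 4 dendritic cell markers, against 4 and 4. List medians moved from 3.29 to 3.25 for neutrophil, 0.78 to 0.83 for monocyte and macrophage and -0.70 to -0.73 for T cell markers and from 0.97 to 1.20 for cytokines, while the median standard errors of these lists rose from 0.38, 0.16, 0.22 and 0.41 to 0.55, 0.20, 0.26 and 0.57.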
